A study of Caenorhabditis elegans with 2 samples.

How the data were processed

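The series held 2 samples, 1 MRG-1 ChIP library and 1 input DNA library from fem-2(b245) adults, and 1 processed file, the peak list of the ChIP sample. Per the labels' protocols, frozen animals were ground before crosslinking, which lasted 10 minutes in 1% formaldehyde. The extract was sonicated and the soluble chromatin precipitated with the antibody. Libraries were made from ChIP DNA and 10 ng of input DNA, and sequenced on Illumina instruments. Per the submitters' processing notes, BWA and the genome build ce10 were used. Per the file headers, the coordinates are those of WormBase WS220, the release behind ce10, and the peaks carry MACS as their source. The versions, the settings of the peak caller and whether the input served as its background are not given in the sources used here. The deposited score of each peak is the authors' own value, with no scale stated in the file. It never fell below 50.02 and 20.9% of the peaks had 3100 or more, so it does not order the strongest peaks well. It was used only to rank, describe and filter peaks within this list.

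Samples were grouped by the ChIP and input labels in their titles. Read counts of either library were not analysed here, so depth, enrichment over input and reproducibility between libraries are not reported. Chromosome length was taken as the end of the last peak on each chromosome, a lower bound, from 13.8 Mb on III to 20.9 Mb on V. A peak was assigned to a chromosome part or bin by its midpoint, and covered length was counted base by base. The centre of a chromosome was its central 50%. Bins were 1 Mb, and summaries over bins left out 3 end bins shorter than 0.5 Mb.

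Densities were compared with two-sided exact binomial tests against the share of length, with 95% Clopper-Pearson intervals turned into density ratios. Medians were compared with permutation tests of 100000 resamples. Bins were permuted between X and autosomes, or between centres and ends within each chromosome. Spacing was compared with 1000 placements of the same peaks, in the same order and without overlap. The binomial tests, Fisher's exact tests and permutations of medians treat peaks as independent. The spacing shows that peaks cluster, so the p-values of these tests are too small. Permutations of bins are given beside the comparison of X with the autosomes over all peaks, and beside most of those of centres with ends over all 5 autosomes. No permutation of bins stands beside the tests of single autosomes, of a central 33%, of X among subsets of the peaks, or of medians. The Fisher tests have none either. Permutations of bins treat single bins as exchangeable and ignore the likeness of neighbouring bins. Their p-values may therefore be too small as well. Tests were run in Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1, and plots drawn with Matplotlib 3.10.9.

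The statistics were tested on simulated data with the number of real peaks (3782) and the real chromosome lengths. In 100 simulations with a true X to autosome ratio of 0.556, the mean estimate was 0.562 and 97% of the intervals held the true value. For a centre to ends ratio of 0.8, the mean estimate was 0.795 and 94% of the intervals held it. With no difference simulated, 6% of the X tests and 8% of the centre tests passed 0.05. The permutation of bins passed in 8% of the simulations without a difference and in 100% of those with one. The spacing test found all simulated lists with 30% of peaks clustered (20 simulations) and called 5% of the lists without clustering. Apart from the clustered lists, simulated peaks were placed independently and evenly within each chromosome part. The real peaks cluster, so the rates of the density and bin tests need not hold for them.

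The groups, the main comparisons with their tests and the rule for naming peaks were fixed before the data were examined. The rule named the 20 peaks with the highest score, the 5 highest on X and the 5 widest, with ties broken by width and then position. Alternatives fixed at the same time were the upper 50% of peaks by score, merging of peaks less than 1 kb apart, leaving out the widest 5% of peaks, a central 33%, covered length in place of counts, permutation of bins, and placement within bins. Added after the data had been seen were the permutation of bins for covered length, the lower 50% by score, merging within 5 kb, permutation of bins for these, for the upper 50%, for merging within 1 kb and without the widest 5%, leaving out 1 autosome at a time or the first 1 Mb of X, the upper 50% and the widest 5% for spacing, and all alternatives for width and score. The score quartiles, the Fisher tests, the tests of each chromosome and the test among the autosomes were also added then. Peaks were not assigned to genes. The gene table at hand is on the assembly WBcel235, another build than that of the peaks, so comparisons with genes, positions within genes, 24 gene lists fixed in advance, closely spaced genes and base composition were not analysed here, and peaks are named by coordinates.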

Results

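Binding of MRG-1 to the genome was measured in Caenorhabditis elegans by chromatin immunoprecipitation followed by sequencing (ChIP-seq). MRG-1 is a chromodomain protein, the worm relative of human MRG15, and is required for germ cell development. The animals were hermaphrodites of the strain fem-2(b245), in which a gene of the sex determination pathway carries a temperature-sensitive mutation. They were described as young adults with a germline, and the labels give a culture temperature of 20 °C. The growth protocol in the labels speaks of gravid adults, a later stage than the stage label. The antibody was an affinity-purified rabbit polyclonal serum raised against an 82-residue MRG-1 peptide. The study held 1 ChIP library and 1 library of input DNA from the same kind of extract. The values analysed here are the authors' peak list for the ChIP library, and there were no replicates. All tests below therefore describe this 1 list: peaks are not biological replicates, and intervals cover counting error only.

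The list held 3782 peaks on the 5 autosomes and the X chromosome, in coordinates of WormBase build WS220. The peaks covered 17.7 Mb, or 17.7% of the length from the chromosome starts to the last peak on each chromosome. Widths ran from 847 to 41889 bp, with a median of 2788 bp and quartiles of 1514 and 6052 bp. The authors' score ran from 50.02 to 3230.05 with a median of 576.7, and 753 peaks had exactly the score 3100. The read depth of the libraries is unknown from this list.

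The first comparison set the X chromosome against the autosomes. MRG-1 peaks were sparse, narrow and low-scoring on X. X carried 195 peaks, or 5.16% of the list (95% exact Clopper-Pearson interval 4.47 to 5.91%), at 11 peaks per Mb. The autosomes carried 3587 peaks at 43.6 per Mb. The density on X was 0.253 times that on the autosomes (95% interval 0.218 to 0.292; two-sided exact binomial test over peaks, p = 2.14e-118). Covered length differed more: peaks lay over 2.32% of X and over 20.9% of the autosomes, a ratio of 0.111. When 1 Mb bins were permuted between X and the autosomes, neither ratio was reached in 100000 resamples (p = 1e-05 for each, the smallest that these permutations can give). The bins of X are neighbours on 1 chromosome, which the permutation ignores, so these p-values may be too small. Of the 18 bins of X, 16 were covered less than the least covered of the 82 autosomal bins, at 3.82%. The median bin was 1.83% covered on X and 19.7% covered on the autosomes.

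**Figure D1:**
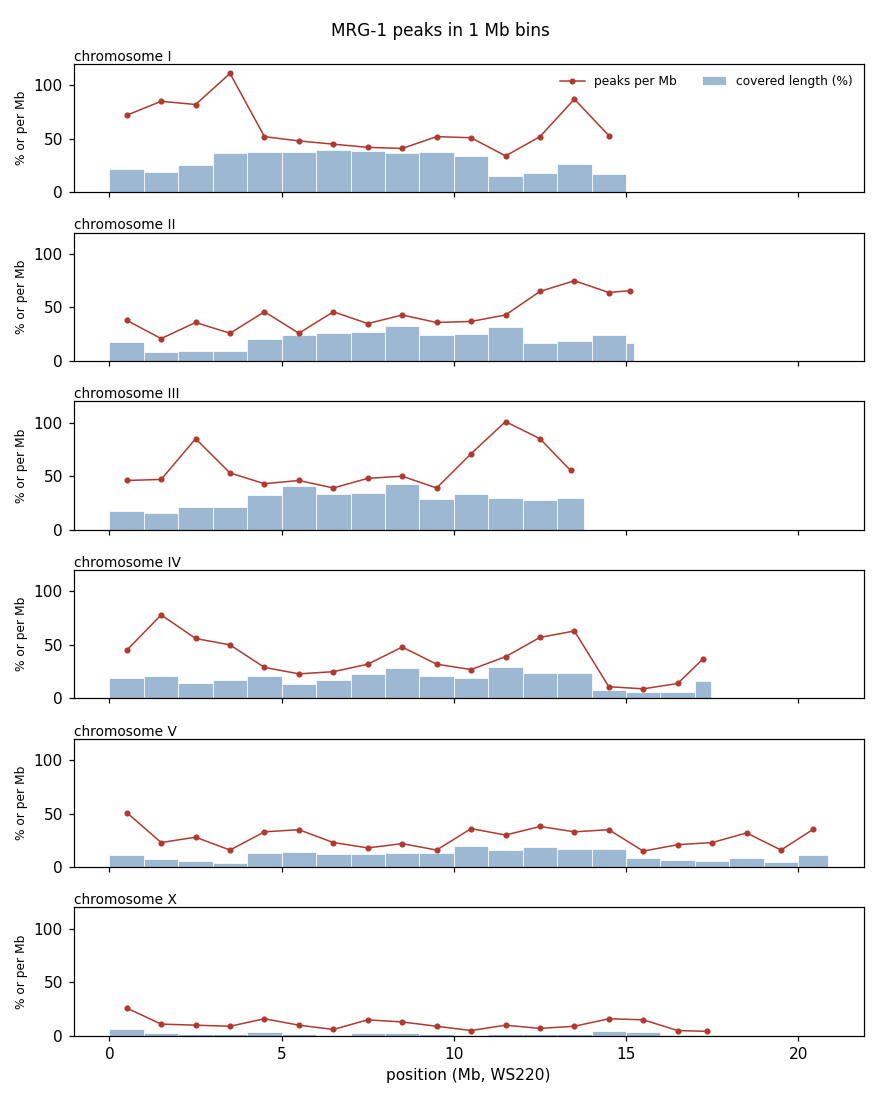
Covered length (bars, percent of each bin) and number of peaks per Mb (points) in 1 Mb bins along the 6 chromosomes, in Mb of WS220, with bins shorter than 0.2 Mb left out. The highest bin of X is its first, at 6.17% covered, and on each of the 5 autosomes the bin with the most peaks per Mb lies in the outer 50%.

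The deficit on X was larger among peaks with high scores. X contributed 65 of the 946 peaks in the lowest score quartile (6.87%), 105 of 945 in the second (11.1%), 24 of 945 in the third (2.54%) and 1 of 946 in the highest (0.106%; exact interval 0.00268 to 0.588%). Among the upper 50% of peaks by score, 25 were on X and 1866 on autosomes, against 170 and 1721 in the lower 50% (Fisher's exact test, two-sided, odds ratio 0.136, p = 5.8e-29). Counted in the upper 50% alone, the density on X was 0.0623 times that on the autosomes (interval 0.0402 to 0.0923). The median X peak was 1835 bp wide and the median autosomal peak 2922 bp, a difference of -1087 bp (two-sided permutation test with 100000 resamples, p = 0.00158, or 0.00316 after Benjamini-Hochberg adjustment over the tests of width and score). The median score was 202.55 on X and 658.67 on the autosomes (the same permutation test, p = 0.00863 before and after adjustment). Within the lower 50% by score the medians stood the other way round, at 1668 bp on X and 1496 bp on the autosomes, and at scores of 189 and 147. X peaks were also the wider ones within each of the 2 lower quartiles (medians of 1287 against 1199 bp, and 2129 against 1954 bp). In the third quartile they were narrower (2956.5 against 4239 bp), as was the 1 X peak of the highest (6871 against 7183 bp). These splits are made on the score itself, with which width rises, so no test is drawn from them. Against peaks in the outer 50% of the autosomes alone, neither the difference in width (-117 bp, permutation p = 0.462) nor that in score (-72.9, permutation p = 0.0703) passed the test.

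Of the 5 X peaks with the highest scores, all but 1 lay towards the left end. The highest, with a score of 3100, spanned 42671 to 49541 and was 6871 bp wide. The second, at 161813 to 167383, had a score of 2078.08. The others of the 5 highest lay at 14102132 to 14106007 (score 1664.28), 2237419 to 2240285 (1345.65) and 1850442 to 1856187 (1324.5). All 5 were in the outer 50% of the chromosome.

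The autosomes also differed from each other. Peaks covered 29.5% of chromosome I, 29.1% of III, 21.1% of II, 18.3% of IV and 11.5% of V. The same order held for the number of peaks per Mb, at 60.5 on I, 57.8 on III, 42.8 on II, 37.5 on IV and 27.5 on V. Over 1 Mb bins, the mean covered share was 29.4% ± 9.22 on I (SD over 15 bins) and 11.5% ± 4.71 on V (SD over 21 bins). The differences among the 5 autosomes were larger than those after bins were shuffled among them (permutation test over 82 bins with 100000 resamples, p = 1e-05, the smallest that these permutations can give). The shuffling ignores the likeness of neighbouring bins, so this p-value may be too small. Chromosome V, the least covered autosome, was still covered 4.97 times as densely as X, at 11.5% against 2.32%.

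The second comparison set the middle of each chromosome (its central 50%) against the outer 50%. On the autosomes, centres had fewer but broader and higher-scoring peaks. Centres held 1536 peaks (37.3 per Mb) and ends 2051 (49.8 per Mb), a ratio of 0.749 (interval 0.70 to 0.80; two-sided exact binomial test, p = 8.2e-18). Covered length went the other way, with 25.5% of the centres and 16.4% of the ends under peaks. The ratio of these shares was 1.55. With whole 1 Mb bins assigned to centre or ends by their midpoint, the ratio was 1.51 for covered length and 0.751 for the number of peaks. Permuting these assignments within chromosomes gave a permutation p of 1e-05, the smallest possible, for covered length and 0.00121 for the number. Centres are runs of neighbouring bins, which the permutation ignores, so these p-values may be too small. After peaks less than 1 kb apart were merged, the ratio of numbers was 0.909 and no longer passed the permutation of bins (permutation p = 0.197). The median peak was 5097 bp wide in centres and 1952 bp in ends. Peaks over 5 kb made up 51% of the peaks in centres, 19.2% in ends and 3.08% on X. Scores of 3100 or more were given to 34.2% of the peaks in centres, 12.9% in ends and 0.513% on X.

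The direction of the count thus depended on which peaks were counted. Of the autosomal peaks in the upper 50% of the list by score, 1111 lay in centres and 755 in ends, a density ratio of 1.47 (interval 1.34 to 1.62, p = 1.68e-16 by the exact binomial test; permutation of bins, p = 1e-05). In the lower 50% by score, centres held 425 and ends 1296, a ratio of 0.328 (interval 0.293 to 0.366; permutation of bins, p = 1e-05). The association between position and score had an odds ratio of 4.49 (Fisher's exact test, two-sided, p = 6.95e-101). By chromosome, the count over all peaks was lower in the centre of I (ratio 0.635), II (0.765) and III (0.618), each with an adjusted p below the 0.05 threshold (exact binomial tests, Benjamini-Hochberg over 6 chromosomes, 8.3e-11, 0.0015 and 8.3e-11). It did not pass on IV (0.866, exact test, adjusted p = 0.108) or on V (1.04, adjusted p = 0.707). In the upper 50% by score, the density was higher in the centre of I (1.37), II (1.52), IV (1.42) and V (2.15), with adjusted p of 0.00241, 0.00028, 0.00241 and 2.97e-10 by the same exact tests. It did not pass on III (1.20, interval 0.981 to 1.46, exact test, adjusted p = 0.0925). Covered length was higher in the centre on each of the 5 autosomes, with ratios of 1.40 on III, 1.46 on II, 1.49 on IV, 1.63 on I and 1.94 on V.

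X did not show a difference between its centre and its ends beyond counting error. Its centre held 87 peaks and its ends 108, a ratio of 0.806 (interval 0.600 to 1.08, two-sided exact binomial test, p = 0.152; permutation of bins, p = 0.512). The covered share was 1.99% in the centre and 2.65% in the ends, and the median width was 1835 and 1843 bp. That the autosomes and X differ in this ratio was not tested.

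**Figure D2:**
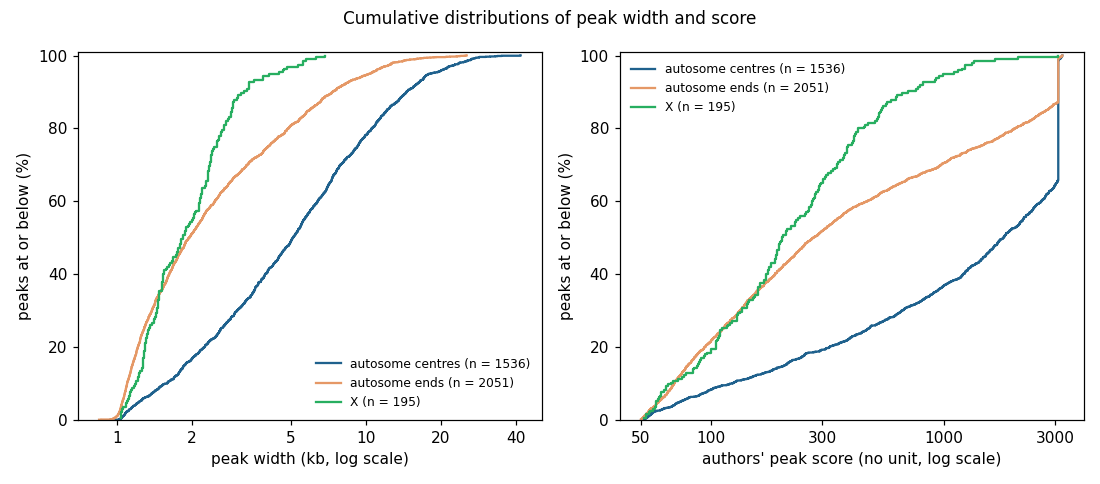
Cumulative share of peaks (percent, vertical axes) by peak width in kb and by the authors' score, both on log axes, for autosome centres, autosome ends and X. Peaks of autosome centres are shifted to larger widths (median 5097 bp, against 1952 bp in ends and 1835 bp on X), and the vertical step at the right is the pile-up of scores at 3100.

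Among single peaks, the 20 with the highest scores (3173.41 to 3230.05) comprised 6 on chromosome I, 5 on IV, 4 on II, 3 on V and 2 on III, with none on X. Exactly 3100 was scored by 753 peaks, 1 of them on X, and only 38 scored higher. Whether those 38 are stronger than the 753 cannot be told from the score, so the 20 need not be the strongest peaks. Of the 20, 12 lay in centres and 8 in ends, and their widths ran from 2312 to 17021 bp. The highest, with a score of 3230.05, lay on III at 11282487 to 11294253 and was 11767 bp wide. It was followed by peaks on II at 10926128 to 10931245 and on I at 13555401 to 13559973, both with a score of 3228.29. The next were on II at 14856704 to 14859015 (3227.04), III at 4306771 to 4320490 (3225.28) and IV at 9856856 to 9866544 (3220.27). The highest peak on V, at 2008416 to 2011807, had a score of 3208.54.

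The 5 widest peaks all lay in autosome centres and had scores well below the highest. The widest, 41889 bp on III at 4906026 to 4947914, had a score of 68.17. The others were on III at 6362159 to 6397275 (35117 bp, score 469.6), I at 6541756 to 6575471 (33716 bp, 293.28), I at 3801602 to 3834720 (33119 bp, 102.89) and II at 7852130 to 7883719 (31590 bp, 514.88).

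The third comparison concerned the spacing of peaks. Neighbouring peaks lay closer together than peaks of the same widths placed at random. The median gap was 4437 bp, against a mean of 12141 bp in 1000 random placements, of which the lowest was 11504 bp (two-sided permutation p = 0.001, the smallest that these placements can give). Gaps under 1 kb made up 30.2% of all gaps and 5.83% of those in the placements. Keeping the number of peaks in each 1 Mb bin hardly raised the latter share, to 6.50%. Whether the short gaps separate different sites or parts of 1 region split into several calls was not tested. In the upper 50% of peaks by score, the median gap was 19044 bp and that of the placements 24672 bp. The median gap was 2498 bp on I, 2984 bp on III, 4651 bp on IV, 5021 bp on II, 8600 bp on V and 48175 bp on X. The longest stretch without a peak was not on X but on IV, from 15648464 to 16401885 (753 kb), and the second longest was on X, from 6265693 to 6836203 (571 kb). Of the 20 longest gaps, 10 were on X.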

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

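The chromosome lengths, read depth and unknown peak caller settings limit all values, and a list of called peaks cannot show binding below the calling threshold. The lower density on X kept its direction and passed its test in the alternatives that gave a test, with ratios from 0.0623 in the upper 50% of peaks by score to 0.336 after merging of peaks less than 1 kb apart. Merging within 5 kb was not run for X against the autosomes. The ratio of covered length was 0.111. Leaving out 1 autosome at a time, added after seeing the data, gave 0.225 to 0.277. The lower number of peaks in autosome centres turned round in the upper 50% by score (1.47) and for covered length. With whole bins assigned to centre or ends, added for covered length after seeing the data, its ratio was 1.51. Merging of peaks less than 5 kb apart, also chosen after seeing the data, turned the number round too (1.24, exact binomial test, p = 1.16e-05). With whole bins, also added afterwards, the upper 50% gave 1.45 (permutation p = 1e-05) and merging within 5 kb 1.23 (permutation p = 0.00041). The lower number in centres kept its direction after merging within 1 kb (0.912, exact binomial test, p = 0.0241), but there it did not pass with whole bins, a setting added afterwards (0.909, permutation p = 0.197). It passed without the widest 5% (0.679; with whole bins, permutation p = 0.00014), in the central 33% (0.785, exact binomial test alone) and under permutation of bins over all peaks (p = 0.00121). The ratio on X passed no test, at 0.667 to 0.914. Peaks were closer than random placements in each alternative run for spacing. The median gap was 0.335 (without the widest 5%) to 0.772 (upper 50% by score) times that of the placements, both settings chosen after seeing the data. Merging of close peaks was not run for spacing, so splitting of broad regions into several calls may contribute to it. In the lower 50% by score, a setting chosen after seeing the data, median X peaks were wider by 172 bp and higher by 41.9 in score than autosomal ones. The split is on the score itself, and the cause was not tested. Against autosome ends alone, also chosen afterwards, the differences in median width (-117 bp, p = 0.462) and score (-72.9, p = 0.0703) no longer passed the permutation test. No paired analysis was possible because each group had 1 library. Alternatives that need genes or sequence were not run. No library could be left out.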

Other observations

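The ratios in the upper 50% of peaks by score and after merging within 1 kb, for X against autosomes and for centres against ends, were chosen before the data were examined. The other tests in this part were chosen after the peak list had been seen, as was the use of those ratios to weigh explanations. None could use a second library. The left end of X stood apart from the rest of that chromosome. Its first 250 kb held 15 peaks and was 17.6% covered, while the next highest of the 71 bins of 250 kb on X reached 8.62% and the median bin 1.60%. The first 250 kb of the autosomes were covered by 14.7% on III, the least, to 32% on I, the most. The last 250 kb of X up to its last peak was 0.508% covered, against 13% to 29.5% at the right ends of the autosomes. None of 10000 random placements of the X peaks had so covered a bin, the highest reaching 12.7% (permutation p = 0.0001, the smallest that they can give). This argues against random scatter of single peaks. The placements do not keep the clustering of neighbouring peaks seen over the list, so they cannot tell this end from ordinary clustering. A single bound region broken only by gaps under 1 kb is argued against for the first 1 Mb, where merging within 1 kb left 21 regions. That number was reached in any 1 Mb bin by a share of 0.0145 of random placements of the merged regions. These placements also lack clustering, and they bear on density, not on splitting across longer gaps. The first 250 kb alone was not tested in this way. Its 15 peaks ran from 33478 to 241162, with none between 61763 and 103791 or between 114520 and 161813. A candidate explanation is a stretch of autosome-like chromatin at this end, which was not tested without gene annotation or read coverage.

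The low density of peaks on X was weighed against 3 technical explanations. The deficit was not confined to calls near the threshold, because the ratio fell from 0.253 to 0.0623 in the upper 50% by score. Sites on X that fell below the threshold are not excluded, since generally lower scores on X would also make the ratio fall. Splitting of broad autosomal regions by gaps under 1 kb does not account for all of the low density, since the ratio after merging within 1 kb was 0.336 with an upper limit of 0.391. A wider merging distance was not tried for X. Fewer reads from X in the library could not be excluded, because the list holds no read coverage. If scores scaled with reads, lower coverage alone would lower all scores on X alike. Peaks with at least 50% of the piled-up score of 3100 were, per Mb of X, 0.0177 times as frequent as peaks at or above 3100 on the autosomes (3 peaks against 790), but that scaling is assumed. The labels give hermaphrodites, which are XX, and the design offers no other group with which to test a biological explanation.

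The larger number of peaks in autosome ends was seen among calls of low score. The ratio of density in centres to that in ends was 0.328 in the lower 50% by score and 1.47 in the upper 50%. This split largely restates that peaks scored lower in ends (median 275.43) than in centres (1801.76), so it is no separate test of an explanation. Whether single bound regions were split into more calls in the ends cannot be told apart from denser separate sites. Merging within 5 kb gave a ratio of 1.24, but merging joins any calls that lie close together. X peaks resembled those of autosome ends at the median, at 1835 and 1952 bp, yet broad members were rarer among them. Peaks over 5 kb were 3.08% on X and 19.2% in autosome ends (Fisher's exact test over peaks taken as independent, odds ratio 0.134, p = 1.12e-10).

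The median score rose with width up to the eighth width decile (5225 to 7141 bp), was the same in the ninth (7146 to 10933 bp) and then fell. The median score was 67.92 in the narrowest width decile and 3100 in the eighth and ninth, then 2801.55 in the widest decile and 1732.3 in the widest 5% (190 peaks of 14354 bp or more). A filter on score would therefore remove some of the broadest regions of the list.

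Chromosome IV was covered unevenly. Because this chromosome carries most genes for 21U-RNAs, the piRNAs of the worm, in 2 broad clusters, stretches inside them were set at 5 to 7 Mb and 14 to 17 Mb from general knowledge, not from an annotation. Peaks covered 10.1% of both stretches together and 21.6% of the rest of the chromosome. As low a value was found in 44 of 1747 circular shifts of the stretches (a share of 0.0252). The result rests on the distal stretch, covered by 6.63% (share of shifts 0.0309). It may depend on the boundaries, set after the peaks had been seen: the bin before this stretch, from 13 to 14 Mb, was 23.5% covered. The proximal one was covered by 15.2% (0.212). The hypothesis that MRG-1 avoids piRNA gene clusters is thus open, since the distal stretch is also part of a chromosome end and holds the longest gap of the list.

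MRG-1 has a role in pairing of meiotic chromosomes. The ends taken as those of the pairing centres were therefore compared with the opposite ends, over the outermost 25% on each side. The ends were assigned from general knowledge, not from an annotation, as the right end on I and III and the left end on II, IV, V and X. The assignment is doubtful for III and V, whose pairing centres may lie at the left and the right end instead. Peaks covered more of the end so assigned on 4 of 6 chromosomes (III, IV, V and X). They covered less of it on I (20.3% against 24.6%) and II (11.6% against 22.7%). With III and V reversed, it would be covered more on IV and X only. For the assignment used, the mean log2 ratio was 0.10 ± 0.63 (SD, n = 6). A two-sided exact sign-flip permutation test gave p = 0.719, where the smallest p it allows is 0.0313. The test was not rerun with III and V reversed, so it cannot decide whether peaks favour pairing centre ends.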
